A study of Homo sapiens with 6 samples.

How the data were processed

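Gene expression was measured in HEL and SET2, a pair of human cell lines that the labels describe as acute myeloid leukemia lines and that are both known to carry an activating mutation of the kinase gene JAK2. Each line was transduced with 1 of 3 lentiviral constructs. These were the empty shRNA backbone pLKO as control, an shRNA directed at IGF1R, the receptor of insulin-like growth factor, and a miR-125a sponge, a transcript whose repeated binding sites are meant to titrate that microRNA. Transduced cells were selected in puromycin for 96 h before RNA was taken with Trizol, per the labels. Biotin-labelled material from each of the 6 cultures was hybridised to 1 GeneChip Human Gene 2.0 ST array.

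The values used were those deposited by the authors in the series table, taken as the authors had processed them and on a log2 scale. The arrays were processed with Affymetrix Expression Console, per the submitters' processing notes. The summarisation, the background correction, the normalisation and the genome build were not given in the sources used here. The log2 scale was read from the values themselves, which ran from 1.61 to 13.99, and the medians of the arrays ran from 5.69 to 5.75. The table held 352859 probe sets per array, each covering part of a gene. Scanner files were not used here, so no probe set could be called present or absent against background, and a fall of signal near the lower end of the scale could not be told from noise.

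The array's own annotation listed a gene for 272340 probe sets. Of these, 259224 carried a single symbol and were averaged per symbol on the log2 scale into 22320 genes, with a median of 9.5 probe sets per gene. The average of 2618 genes rested on 1 probe set. A further 13116 probe sets carried several symbols and 80519 had no listed gene; both sets were left out of the gene averages. The symbols were kept as annotated, some of them old, and 20529 were found in a RefSeq table of the GRCh38.p14 assembly. That table served only for chromosomes and for the order of neighbouring genes. No coordinates are given, because the build behind the array values was unknown. Genes of the Y chromosome and XIST were left unnamed by rule.

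The numbers that pair arrays across treatments stand for cell lines, replicate 1 being HEL and replicate 2 being SET2. The 2 cell lines were the only replication, with 1 array per line and treatment. All 6 arrays were fitted gene by gene in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with treatment and cell line as terms, so that each treatment was compared within lines. The fit left 2 residual degrees of freedom, to which eBayes added 4.78 prior degrees of freedom. P-values of single genes therefore rest on how far the lines differed in their response, and the number of arrays limits the precision of every value. The contrasts were IGF1R shRNA against control, sponge against control, sponge against IGF1R shRNA, and HEL against SET2. P-values were two-sided and adjusted by Benjamini-Hochberg over all 22320 genes, with 0.05 as threshold. Tables were handled with data.table (version 1.17.8) and pandas (version 2.3.3), and plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

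Before the data were examined, 24 gene lists were fixed, with 581 entries, of which 544 were measured as single-symbol genes. They covered IGF-1 and insulin signalling, FOXO target genes, the ATF4 and amino acid response, cholesterol synthesis, JAK2-STAT5 targets, ERK feedback and immediate early genes, mitosis, DNA replication, ribosome biogenesis, glycolysis and hypoxia, p53 targets, the BCL2 family and apoptosis, heat shock and chaperones, proteasome subunits, ER stress and ERAD, the interferon response, NF-kB and cytokines, erythroid genes, megakaryocyte and platelet genes, monocyte and granulocyte genes, lymphoid genes, stem cell and progenitor genes, published miR-125 targets, and the ZFAND family. Each list was tested against all other genes with camera from limma at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 24 lists of a contrast. Beside it stand camera with a correlation estimated from the residuals, and fry, which asks whether the genes of a list move one way on balance. Within a line, the median change of a list was placed as a percentile among those of 10000 random lists of the same size and matched expression, which is a description and not a test. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

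The genes to be named were set by a rule fixed in advance. It took IGF1R, ZFAND2B, and for each contrast the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with the same sign in both lines (for HEL against SET2, under each treatment). Where fewer passed, genes were ranked by the smaller of their changes in the lines, provided that the signs matched and that the mean level reached the median of all genes, 5.55. Small RNAs, unnamed loci and receptor segments were not named by rank. Up to 4 members per list were added, those with the largest average changes of the same sign in both lines.

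Correlations of changes were computed across genes, which are not independent replicates, and carry no p-values. Both treatments were compared with the same 2 control arrays. The correlation this alone produces was measured in 100 simulated data sets with no treatment effect and the same spread in every group. The test was also tried on simulated data. In 5 draws, log2 changes were added to 500 genes in total at each size, and the fit recovered 96.8% of the changed genes at a log2 change of 2 and 30.8% at 1 for the shRNA contrast, and 95.8% and 31.8% for the sponge contrast, with 33 and 38 false calls over the 5 draws. A list shifted by -0.5 was called in 10 of 10 draws with the preset correlation and in 0 of 10 with the estimated correlation, at 0 calls among 230 unshifted lists. The estimated correlation therefore had little power at this number of arrays. The simulated genes varied independently, so these draws do not show how the preset correlation performs on lists whose genes vary together. In the data the estimated correlation ran from -0.13 (ZFAND family) to 0.94 (cholesterol synthesis). It was 0.24 for the ATF4 list, 0.28 for DNA replication and -0.019 for JAK2-STAT5 targets, against the preset 0.01.

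The alternatives tried were quantile normalisation and centring of the deposited arrays, and the median or brightest probe set in place of the mean. Others were leaving out dim genes, eBayes with trend and robust variances, and each array left out in turn. Each line alone, only the 4 arrays of a contrast, and no cell line term were also tried. Testing each named probe set by itself was added after the data had been seen. The source label of the sponge arrays names miR-125a itself, whereas their title, their treatment label and the design text name the sponge. They are treated here as sponge arrays. If the source label were right, a rise under the sponge would be a rise under the microRNA.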

Results

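Transcript levels were measured on 6 arrays, 3 from HEL and 3 from SET2. HEL is an erythroleukemia line, and SET2 derives from a leukemia that followed a myeloproliferative neoplasm. In each line 1 array was labelled control, 1 IGF1R shRNA and 1 miR-125a sponge. The study concerns AIRAPL, the proteasome-associated zinc finger protein encoded by ZFAND2B, whose loss it relates to myeloid transformation and IGF-1 signalling. The sponge was directed at a microRNA and the shRNA at the IGF-1 receptor. Median log2 values of the arrays lay between 5.69 and 5.75. Across genes, treated arrays correlated with the control of their line at 0.977 (HEL, IGF1R shRNA), 0.991 (HEL, sponge), 0.987 (SET2, IGF1R shRNA) and 0.993 (SET2, sponge). Arrays of the same label correlated at 0.924 to 0.932 between the lines.

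The first question was whether the targeted transcript was lowered. IGF1R was not detectably lower in the arrays labelled IGF1R shRNA. In HEL its log2 level was 8.63 in the control and 8.56 in the array labelled IGF1R shRNA, and in SET2 it was 8.32 and 8.33. The average change was -0.032 (SE 0.15, 2 lines, 95% confidence interval -0.38 to 0.31, adjusted p = 0.973), and the lower end of this interval corresponds to 77.0% of the control level. Of the 22 IGF1R probe sets, 15 had a mean log2 level of 8 or more, and their median change was 0.10 in HEL and 0.03 in SET2. Averaged over the lines, these 15 probe sets ran from -0.18 to 0.35. Among all 22, 5 were lower and 7 higher in both lines. A pair of dimmer probe sets was lower in both lines. The log2 changes were -2.51 and -1.43 for 16805504, and -0.96 and -1.57 for 16805532. The gene average turned to 0.15 when the median of the probe sets was taken, and to 0.042 without IGF1R shRNA replicate 1. Because no fall of the target was detected, these arrays are called by their label throughout. Every direction given for them compares labelled arrays and not cells shown to lack IGF1R. In the sponge arrays IGF1R stood at 8.81 in HEL and 8.37 in SET2, an average change of 0.12 (SE 0.15, adjusted p = 1). It was 0.033 without sponge replicate 1, 0.20 without sponge replicate 2, 0.065 with the median of the probe sets and -0.005 with the brightest.

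ZFAND2B, listed among published targets of miR-125, did not pass the test under the sponge. Its log2 level in HEL was 6.80 in the control and 6.64 in the sponge array, and in SET2 it was 5.67 and 5.68. The average change was -0.0715 (SE 0.17, 95% confidence interval -0.47 to 0.33, adjusted p = 1), and without control replicate 1 it was 0.088. Of its 20 probe sets, 4 had a mean log2 level of 8 or more. Their median change under the sponge was -0.145 in HEL and -0.30 in SET2. Among all 20, 6 were lower and 4 higher in both lines under the sponge. In the arrays labelled IGF1R shRNA the gene's level was 6.45 in HEL and 5.80 in SET2, an average change of -0.11 (SE 0.17, adjusted p = 0.900). That average became 0.049 without control replicate 1 and 0.082 without IGF1R shRNA replicate 1. In these arrays the 4 brighter probe sets had a median change of -0.44 in HEL and 0.24 in SET2. The lines themselves differed. ZFAND2B was higher in HEL than in SET2 by 0.91 (SE 0.14, adjusted p = 0.00377), while IGF1R differed by 0.33 (adjusted p = 0.094).

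**Figure D1:**
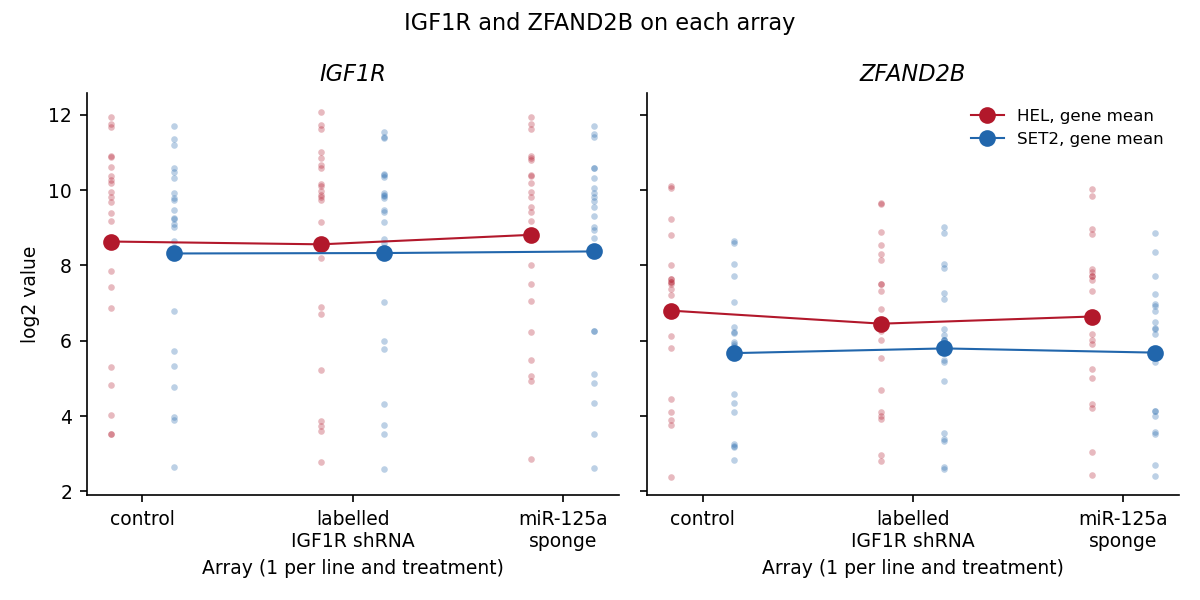
Log2 values of IGF1R (left) and ZFAND2B (right) on each of the 6 arrays; large points joined by lines are the gene means of 1 line and small points are single probe sets. The IGF1R mean stays between 8.32 and 8.81 on every array, and the ZFAND2B mean of each HEL array lies above that of each SET2 array.

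The arrays labelled IGF1R shRNA were set against control to find genes that differ where an shRNA against the IGF-1 receptor was introduced. The receptor's transcript was not detectably lower in them. Genes of the ATF4 and amino acid response, which make or import amino acids when supply is short, fell as a group, by a mean log2 change of -0.64 over 21 genes, and 17 of them were lower in both lines (adjusted p = 8.05e-09 by camera, adjusted p = 0.657 with an estimated correlation). Targets of JAK2-STAT5 signalling, DNA replication genes, ribosome biogenesis genes, erythroid genes and monocyte and granulocyte genes also fell as groups at the preset correlation, by means of -0.16 to -0.27. None of these 5 calls held with an estimated correlation (adjusted p = 0.657 to 0.724), and each was lost when some single array was left out. Among single genes ranked by the smaller of the changes in the lines, the first upward was THBS1, the secreted glycoprotein thrombospondin, at 1.90 (SE 0.28, 2 lines), and the first downward were STAR, a mitochondrial cholesterol carrier, at -1.88 (SE 0.18), and PRF1, the pore-forming protein perforin, at -1.92 (SE 0.16). No single gene passed the test.

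Limma called 0 of 22320 genes after Benjamini-Hochberg adjustment, with 1656 at unadjusted p under 0.05 where 1116 would arise by chance. The estimate of the spread is shared with the sponge arrays, whose changes spread less (SD 0.24 in HEL and 0.22 in SET2, against 0.39 and 0.30). This can enlarge the count, so the excess over 1116 is not by itself evidence of an effect. The smallest adjusted p was 0.158, shared by STAR, PRF1 and ETV4. STAR stood at -1.88 in each line. PRF1 stood at -1.70 in HEL and -2.14 in SET2, and ETV4, an ETS factor induced by ERK signalling, at -1.50 and -1.44. The other named genes with negative values were the actin regulator CORO1A (-1.35), KLHL2 (-1.06), the growth factor gene PDGFD (-1.15), CYFIP2 (-1.06), GCKR (-1.25), TM6SF1 (-1.10) and SESN2 (-1.20). Those with positive values, besides THBS1 (2.54 in HEL and 1.27 in SET2), were AP5Z1 (1.14, from 1 probe set), the GTPase gene RHOB (1.11), the sphingolipid receptor gene S1PR1 (1.28), SLC10A5 (0.77), PLXDC2 (0.997), ARID5B (0.87), the ubiquitin ligase gene CBLB (0.72), IQGAP2 (0.74) and RASD1 (0.71), and these genes and those with negative values, 17 in all, had an adjusted p of 0.560. Several of these averages depend on how probe sets are combined. With the brightest probe set in place of the mean, RHOB stood at 0.065, SESN2 at -0.22, PLXDC2 at 0.40, RASD1 at 0.43, ARID5B at 0.52 and PDGFD at -1.78, and with the median of the probe sets CBLB stood at 0.39. Without IGF1R shRNA replicate 1, S1PR1 stood at 0.82 and SESN2 at -0.77. A log2 change of at least 1 on average with the same sign in both lines was seen for 29 genes upward and 45 downward. Taken within lines, 298 genes were at least 2-fold higher and 290 lower in HEL, against 70 and 99 in SET2. The count of 0 became 729 without IGF1R shRNA replicate 2, when the HEL array alone carries the label and is assumed to vary like the other groups; 15 of the 20 named genes then passed, with adjusted p from 0.0116 to 0.0414.

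The mean of the ATF4 list was -0.93 in HEL and -0.35 in SET2, and its median lay at percentiles 0.0 and 1.18 of the random lists. Of its 21 members 0 passed over all genes and 6 passed adjusted over the list alone. These were ASNS, PHGDH and PSAT1, which make asparagine and serine, ATF3, the mTORC1 inhibitor DDIT4, and SESN2. DDIT4 had an average of -1.84 (SE 0.56), from -3.11 in HEL and -0.56 in SET2. The cystine transporter gene SLC7A11 stood at -3.08 and -0.16, and CHAC1, which degrades glutathione, at -2.44 and -0.52. The list's mean was -0.32 without IGF1R shRNA replicate 1 and still past the threshold (adjusted p = 0.000752).

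**Figure D2:**
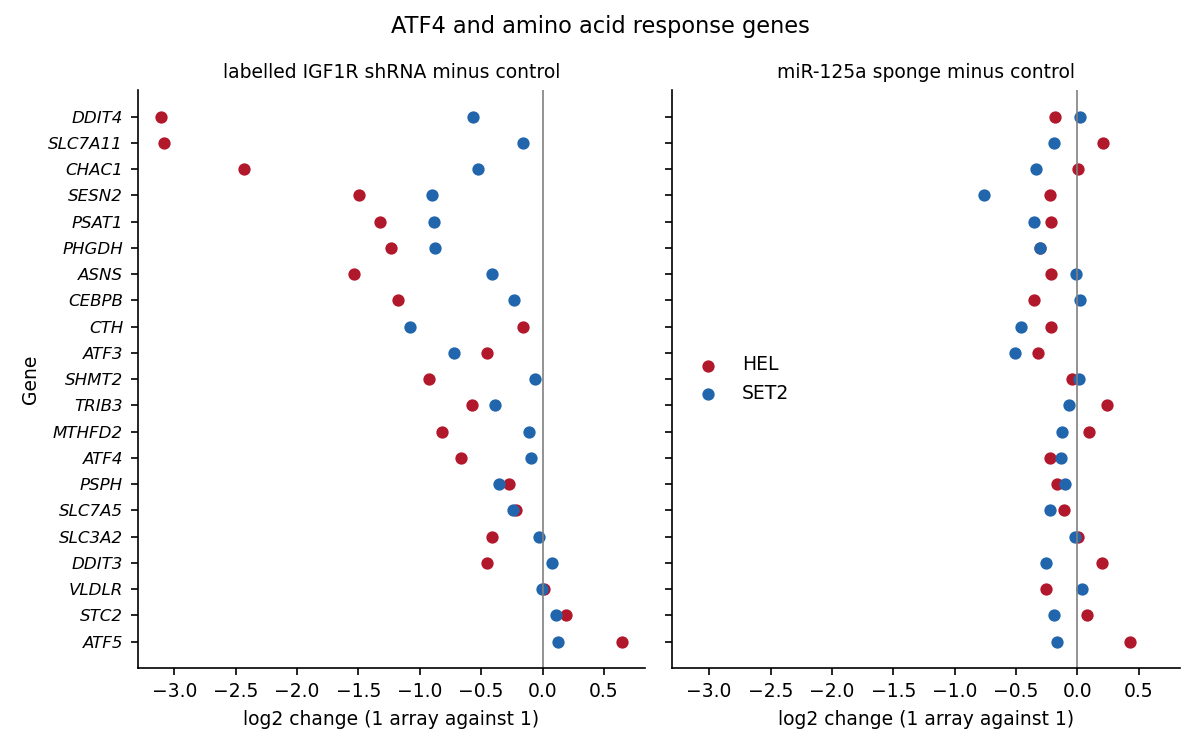
Log2 change of each gene of the ATF4 and amino acid response list in HEL and SET2, for the arrays labelled IGF1R shRNA (left) and the miR-125a sponge arrays (right), each value being 1 array minus the control array of its line. On the left 17 of the 21 genes are below 0 in both lines, with DDIT4 at -3.11 in HEL and -0.56 in SET2; on the right 9 are.

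The other 5 called lists moved less. DNA replication genes fell by a mean of 0.19 (25 genes, 23 with a negative average and 11 lower in both lines, adjusted p = 0.00239, adjusted p = 0.724 with an estimated correlation), from -0.063 in HEL and -0.33 in SET2; examples are the cyclin gene CCNE1 (-0.60), the helicase genes MCM3 (-0.41) and MCM6 (-0.41) and the nucleotide reductase gene RRM2 (-0.40). JAK2-STAT5 targets had a mean of -0.27 (16 genes, 13 negative and 9 lower in both lines, adjusted p = 0.00465, adjusted p = 0.657 with an estimated correlation), with ID1 at -0.59, the kinase gene PIM1 at -0.58, STAT5B at -0.47 and OSM at -0.41. Ribosome biogenesis genes had a mean of -0.19 (20 genes, 18 negative and 8 lower in both lines, adjusted p = 0.00465, adjusted p = 0.657 with an estimated correlation), with WDR12 at -0.46, PES1 at -0.42, MYC at -0.37 and RRS1 at -0.34. Erythroid genes had a mean of -0.21 (29 genes, 23 negative and 14 lower in both lines, adjusted p = 0.00906, adjusted p = 0.657 with an estimated correlation). Their median lay at percentile 0.25 of the random lists in HEL but at 69.22 in SET2. The embryonic globin gene HBZ stood at -1.22 and RHD at -0.58, but ERMAP at 0.45 and KEL at 0.40. Monocyte and granulocyte genes had a mean of -0.16 (26 genes, 19 negative and 9 lower in both lines, adjusted p = 0.0460, adjusted p = 0.657 with an estimated correlation), with MS4A3 at -0.74, CD33 at -0.56, TYROBP at -0.51 and MPO at -0.42. Of the 6 called lists fry called the monocyte and granulocyte list alone (adjusted p = 0.0423). In these 5 lists 0 members passed over all genes, and adjusted over the list alone MS4A3 passed and no other.

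Each of these 5 calls was lost when some single array was left out, in part with a mean nearer 0 and in part with a mean as large as before. Without IGF1R shRNA replicate 2 the mean was -0.059 for DNA replication (adjusted p = 0.739), -0.21 for JAK2-STAT5 targets (adjusted p = 0.183), -0.12 for ribosome biogenesis (adjusted p = 0.314) and -0.13 for monocyte and granulocyte genes (adjusted p = 0.218). Without IGF1R shRNA replicate 1 it was -0.10 for erythroid genes (adjusted p = 0.440) and -0.19 for monocyte and granulocyte genes (adjusted p = 0.0892), the latter no nearer 0 than the -0.16 of all arrays. Without control replicate 2 it was -0.13 for DNA replication (adjusted p = 0.112), -0.21 for JAK2-STAT5 targets and -0.16 for ribosome biogenesis (both adjusted p = 0.0835), -0.23 for erythroid genes (adjusted p = 0.0521; -0.21 with all arrays) and -0.14 for monocyte and granulocyte genes (adjusted p = 0.0887). Without control replicate 1 the monocyte and granulocyte genes had a mean of -0.19 (adjusted p = 0.0993). With dim genes left out, erythroid genes (-0.18, adjusted p = 0.168) and monocyte and granulocyte genes (-0.21, adjusted p = 0.141) no longer passed.

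The remaining 18 lists did not pass. Mitosis genes had a mean of -0.14 (adjusted p = 0.0710), with AURKA at -0.83 and BIRC5 at -0.61, and proteasome subunits, the machinery AIRAPL binds, a mean of -0.11 (adjusted p = 0.0814). The BCL2 family had a mean of -0.13 (adjusted p = 0.111), and BCL2 itself, at -0.95 in HEL and -0.76 in SET2, passed adjusted over the list alone. Adjusted p was 0.213 for FOXO targets (mean 0.10; SESN3 0.59), 0.232 for p53 targets (-0.15; GDF15 -0.76), 0.296 for glycolysis and hypoxia (-0.091; VEGFA -0.60) and 0.356 for lymphoid genes (-0.10; CD79A -0.89). IGF-1 and insulin signalling genes had a mean of 0.0084 (adjusted p = 0.886), with IGFBP7 at 0.49 and PIK3CD at -0.37. Megakaryocyte and platelet genes had a mean of 0.03 (adjusted p = 0.886), and THBS1, MYL9 (0.64) and CD9 (-0.61) passed adjusted over the list alone. ERK feedback and immediate early genes had a mean of 0.0056 (adjusted p = 0.901), with ETV4, which passed adjusted over the list alone, at -1.47 and JUN at 0.87. Adjusted p was 0.613 for NF-kB and cytokines (mean 0.017), 0.802 for stem cell genes (-0.017; GATA2 -0.86), 0.856 for heat shock (-0.009), 0.901 for published miR-125 targets (-0.022) and 0.955 for the ZFAND family (0.011; ZFAND4 0.66). In no list did a member pass over all genes, and adjusted over the list alone 0 members passed in the lists for which none is named.

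Cholesterol synthesis, ER stress and interferon genes stood on opposite sides in the lines. Cholesterol synthesis genes had a mean of 0.63 in HEL (percentile 100) and -0.43 in SET2 (percentile 0.0), which left the average at 0.099 (adjusted p = 0.308). HMGCS1, an early enzyme of the pathway, stood at 1.29 in HEL and -0.83 in SET2. Genes of ER stress and ERAD had means of 0.25 and -0.17 (adjusted p = 0.384), and interferon response genes 0.19 and -0.23 (adjusted p = 0.584). Single arrays turned calls here as well. Cholesterol synthesis passed at -0.39 (adjusted p = 1.74e-05) without IGF1R shRNA replicate 1, at 0.59 (adjusted p = 4.79e-08) without IGF1R shRNA replicate 2 and at 0.40 (adjusted p = 0.00113) without control replicate 2. Without IGF1R shRNA replicate 1 the proteasome (-0.21, adjusted p = 0.00188) and interferon lists (-0.21, adjusted p = 0.00436) passed, and without IGF1R shRNA replicate 2 ER stress and ERAD (0.23, adjusted p = 0.00536). Without control replicate 1, mitosis (adjusted p = 0.0094), glycolysis and hypoxia (adjusted p = 0.0459) and the proteasome (adjusted p = 0.0459) passed, each with a negative mean. Mean and median differed in sign for IGF-1 and insulin signalling, megakaryocyte genes, stem cell genes and the ZFAND family, and camera and fry differed in direction for IGF-1 and insulin signalling and for the ERK list.

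**Figure D3:**
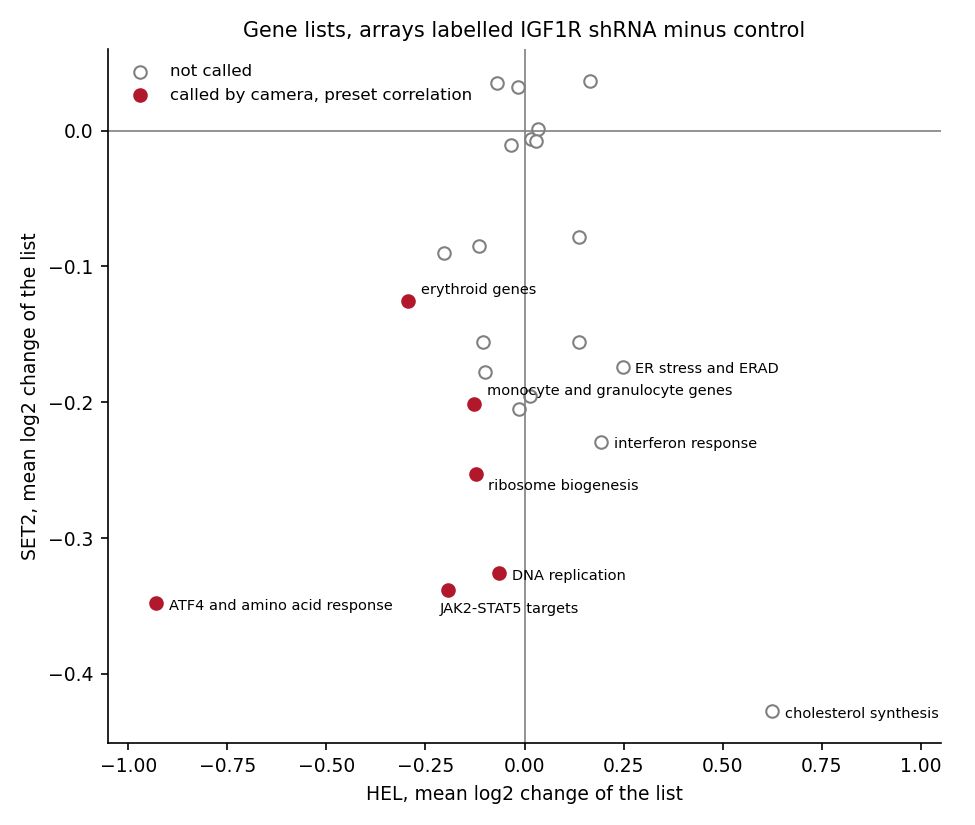
Mean log2 change of each of the 24 gene lists in HEL (horizontal axis) and SET2 (vertical axis), arrays labelled IGF1R shRNA minus control; filled points passed camera with the preset correlation. The 6 filled points lie below 0 on both axes, and cholesterol synthesis lies at 0.63 in HEL and -0.43 in SET2.

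The miR-125a sponge was set against control to find the genes released or lowered when the microRNA is bound. Neither single genes nor gene groups passed the test. Published targets of miR-125 had a mean log2 change of 0.014 over 27 genes, 17 of them with a positive average (adjusted p = 0.727 by camera). Among them LIN28A, a regulator of microRNA maturation, stood at 0.24 (SE 0.14, 2 lines) and the phosphatase gene PPP1CA at -0.29 (SE 0.15). Whether the microRNA bound by this sponge acts on the listed genes in these lines was not tested. The mean of the list therefore does not show whether the sponge worked. Ranked by the smaller of the changes in the lines, the first genes were PALM2, at 1.18 (1.25 in HEL and 1.11 in SET2, SE 0.17), and ABHD14A-ACY1, at -0.78 (-0.84 and -0.71, SE 0.15).

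Limma called 0 of 22320 genes after Benjamini-Hochberg adjustment, with 412 at unadjusted p under 0.05 where 1116 would arise by chance. The smallest adjusted p was 0.579. All contrasts share an estimate of the spread, and the log2 changes spread less under the sponge (SD 0.24 in HEL and 0.22 in SET2) than under IGF1R shRNA (0.39 and 0.30). A count below chance means that the test is conservative for the sponge, so the absence of calls does not show the absence of an effect. The named genes had adjusted p of 0.999 to 1, and 18 of the 20 rested on 5 or fewer probe sets. Positive values besides PALM2 were those of CCL27 (0.80), PLGLB1 (1.20), the taste receptor gene TAS2R19 (0.83), HSD17B7 (0.72), KRTAP10-5 (0.77), HEPACAM (0.76), AP5Z1 (0.61), MRPS28 (0.57) and AGAP8 (0.48). Negative values besides ABHD14A-ACY1 were those of CBWD7 (-1.01), TYW1 (-0.69), PRRG4 (-0.64), NEURL4 (-0.63), the metallothionein gene MT1F (-0.55), BEX1 (-0.80), the DNA repair gene NHEJ1 (-0.68), RAB40B (-0.51) and SLC25A53 (-0.52). With the brightest probe set in place of the mean, MRPS28 (-0.08), NEURL4 (0.19) and MT1F (0.28) turned sign, and with the median of the probe sets HSD17B7 did (-0.03). The brightest probe set also left TYW1 at -0.075, RAB40B at -0.08, CCL27 at 0.085, PRRG4 at -0.16, NHEJ1 at -0.18, ABHD14A-ACY1 at -0.24, HSD17B7 at 0.44 and TAS2R19 at 0.51, and put PALM2 at 1.80. With the median of the probe sets MRPS28 stood at 0.14, RAB40B at -0.20, CCL27 at 0.26 and NHEJ1 at -0.36. Without sponge replicate 1, PLGLB1 stood at 0.41, TYW1 at -0.22 and CCL27 at 0.53; without sponge replicate 2, PLGLB1 stood at 1.99, TYW1 at -1.15 and NHEJ1 at -0.44. BEX1 stood at -1.29 without control replicate 1 and at -0.32 without control replicate 2, HEPACAM at 0.49 without the former and TYW1 at -0.42 without the latter. A log2 change of at least 1 on average with the same sign in both lines was seen for 9 genes upward and 4 downward.

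Camera called 0 of 24 lists, and 0 with an estimated correlation (smallest adjusted p = 0.967) or by fry (0.296). The lowest adjusted p, 0.106, was shared by the ATF4 list (mean -0.13; SESN2 -0.49, ATF3 -0.42) and the proteasome subunits (mean -0.095; PSMC3 -0.31, PSMB1 -0.29). For the ZFAND family adjusted p was 0.888, and for IGF-1 and insulin signalling genes 0.934, with IGFBP7 at 0.27 and INSR at -0.20. Over all genes and adjusted over the list alone, 0 members of any list passed. Leaving out 1 array brought lists past the threshold each time. The ATF4 list passed at -0.13 without IGF1R shRNA replicate 1 or 2, at -0.25 without control replicate 2 and at -0.34 without sponge replicate 1. Without sponge replicate 1 erythroid genes (-0.17) passed as well. The ATF4 list did not pass without control replicate 1 (-0.019) or without sponge replicate 2, where its mean turned to 0.071. Cholesterol synthesis passed at -0.33 without control replicate 1 (adjusted p = 0.00471) and at 0.26 without control replicate 2 (adjusted p = 0.0164), and DNA replication (-0.17) and proteasome subunits (-0.15) passed without sponge replicate 2 (adjusted p = 0.0336 for both). Mean and median differed in sign for FOXO targets, NF-kB and cytokines, stem cell genes and the ZFAND family. Camera ranked IGF-1 and insulin signalling, ERK feedback and the BCL2 family upward at negative means and medians. It compares a list with all other genes, and the means of these lists lay above the -0.0154 of all genes.

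The direct comparison of sponge with IGF1R shRNA arrays asked whether the treatments differed from each other without passing through the controls. The ATF4 and amino acid response stood higher in the sponge arrays by a mean of 0.50, with 18 of 21 genes higher (adjusted p = 4.86e-06 by camera, adjusted p = 0.813 with an estimated correlation, adjusted p = 0.427 by fry). Mitosis genes (0.17, 20 of 24 higher), JAK2-STAT5 targets (0.20, 12 of 16) and ribosome biogenesis genes (0.14, 16 of 20) were higher as groups as well at the preset correlation (adjusted p = 0.0113, 0.0203 and 0.0203). For each of these 3 lists adjusted p = 0.813 with an estimated correlation and adjusted p = 0.427 by fry. Adjusted over the list alone, PHGDH (0.75) and PSAT1 (0.82), enzymes of serine synthesis, passed in the ATF4 list, and 0 members passed over all genes. Limma called 0 of 22320 genes, with 1528 at unadjusted p under 0.05 and a smallest adjusted p of 0.310; without IGF1R shRNA replicate 2 the count was 670. Outside the called lists, ETV4, BCL2, THBS1 and MS4A3 passed adjusted over the list alone.

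The calls of the 3 smaller shifts between the treatments again depended on single arrays, in part without a smaller mean. Mitosis did not pass without IGF1R shRNA replicate 1 (0.16, adjusted p = 0.0571), without IGF1R shRNA replicate 2 (0.18, adjusted p = 0.0739) or with dim genes left out (0.17, adjusted p = 0.0618), where the mean stayed near the 0.17 of all arrays, nor without sponge replicate 1, where it was 0.089 (adjusted p = 0.40). JAK2-STAT5 targets did not pass without IGF1R shRNA replicate 2 (0.14, adjusted p = 0.306) or sponge replicate 2 (0.20, adjusted p = 0.0818), the latter mean being as with all arrays. Ribosome biogenesis did not pass without IGF1R shRNA replicate 2 (0.077, adjusted p = 0.384) or sponge replicate 2 (0.11, adjusted p = 0.227), or with dim genes left out (0.14 as before, adjusted p = 0.10). The ATF4 list passed in each case, with means from 0.18 without IGF1R shRNA replicate 1 (adjusted p = 0.0338) to 0.83 without IGF1R shRNA replicate 2. Lists that passed only with an array left out were DNA replication (without IGF1R shRNA replicate 1, 0.24, adjusted p = 0.000375; without sponge replicate 1, 0.18, adjusted p = 0.00859) and the interferon response (without IGF1R shRNA replicate 1, 0.17, adjusted p = 0.0338). ER stress and ERAD passed without IGF1R shRNA replicate 2 (-0.27, adjusted p = 0.00255), and erythroid genes without IGF1R shRNA replicate 2 (0.23, adjusted p = 0.0423) or sponge replicate 2 (0.21, adjusted p = 0.0474). Cholesterol synthesis passed without IGF1R shRNA replicate 1 (0.36, adjusted p = 1.69e-05), IGF1R shRNA replicate 2 (-0.63, adjusted p = 2.44e-08) or sponge replicate 2 (-0.33, adjusted p = 0.0143). Mean and median differed in sign for proteasome subunits, NF-kB and cytokines and stem cell genes, and camera ranked the ERK and interferon lists upward although their means were negative.

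Changes in HEL were nearly uncorrelated with changes in SET2. Across 22320 genes, the change in HEL correlated with the change in SET2 at 0.0093 for the arrays labelled IGF1R shRNA and at 0.018 for the sponge. Unlike treatments gave -0.0162 (HEL IGF1R shRNA with SET2 sponge) and -0.03 (HEL sponge with SET2 IGF1R shRNA). In both lines the sign was the same for 49.5% of genes under IGF1R shRNA and for 50.8% under the sponge. Among the 11160 brighter genes the lines correlated at 0.028 for IGF1R shRNA and at 0.0707 for the sponge. Each change is 1 array minus 1, with no replicate within a line, and noise of single arrays lowers such correlations. They therefore do not show that the lines respond differently. Within a line the treatments, which share a control array, correlated at 0.352 in HEL and 0.451 in SET2. Their average changes correlated at 0.365, against 0.501 (range 0.487 to 0.514) for shared controls alone in simulation. Their covariance was 0.0151 against 0.0168 (range 0.0162 to 0.0176). The simulation gave every group the same spread, whereas changes spread more under IGF1R shRNA (SD 0.39 in HEL and 0.30 in SET2) than under the sponge (0.24 and 0.22). Unequal spread by itself lowers such a correlation, so neither gap shows how alike the treatments are. With 0 calls in either treatment no overlap could be counted.

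HEL and SET2 were compared to place the lines beside each other, with 3 arrays each. HEL carried more transcript of megakaryocyte and platelet genes, by a mean log2 difference of 1.17 over 32 genes, and of the ATF4 and amino acid response, by 0.81 (adjusted p = 0.586 and adjusted p = 0.655 with an estimated correlation). SET2 carried more of the interferon response (-0.81), of IGF-1 and insulin signalling genes (-0.45), of cholesterol synthesis genes (-0.59) and of proteasome subunits (-0.25). These lists passed camera at the preset correlation and not with an estimated correlation (adjusted p = 0.848 for cholesterol synthesis, adjusted p = 0.655 for the other 3). Single genes differed by up to 7.26, the value of F2RL2, a thrombin receptor family gene that stood at 11.22 to 12.02 on the HEL arrays and at 4.24 to 4.41 on the SET2 arrays. Limma called 5475 of 22320 genes, 2582 higher and 2893 lower in HEL, with 7772 at unadjusted p under 0.05.

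The named genes higher in HEL, after F2RL2, were MLLT3 (5.94), a chromatin reader of blood stem cells, the embryonic globin gene HBE1 (5.38), CAAP1 (4.63), the platelet adhesion gene SELP (4.50), CR1L (4.50), HOXB9 (4.47), CLVS2 (4.36), FOCAD (4.26) and FREM1 (4.13). Those lower in HEL were MYO16 (-5.86), GTSF1 (-5.69), the surface enzyme gene CD38 (-5.57), DOCK8 (-5.52), ENPP3 (-4.92), the amyloid precursor gene APP (-4.80), the class II antigen gene HLA-DRA (-4.57), SLITRK6 (-4.39), ADAMTS1 (-4.33) and T1560 (-4.31), a symbol of the array annotation. Their standard errors ran from 0.117 to 0.270 and their adjusted p from 3.63e-06 to 9.90e-05. With the brightest probe set CAAP1 stood at 2.11, HOXB9 at 2.86 and T1560 at -6.47. The count of 5475 was 3214 without control replicate 1 or without control replicate 2, 2871 without sponge replicate 1 or without sponge replicate 2, and 2613 with the brightest probe set of each gene.

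**Figure D4:**
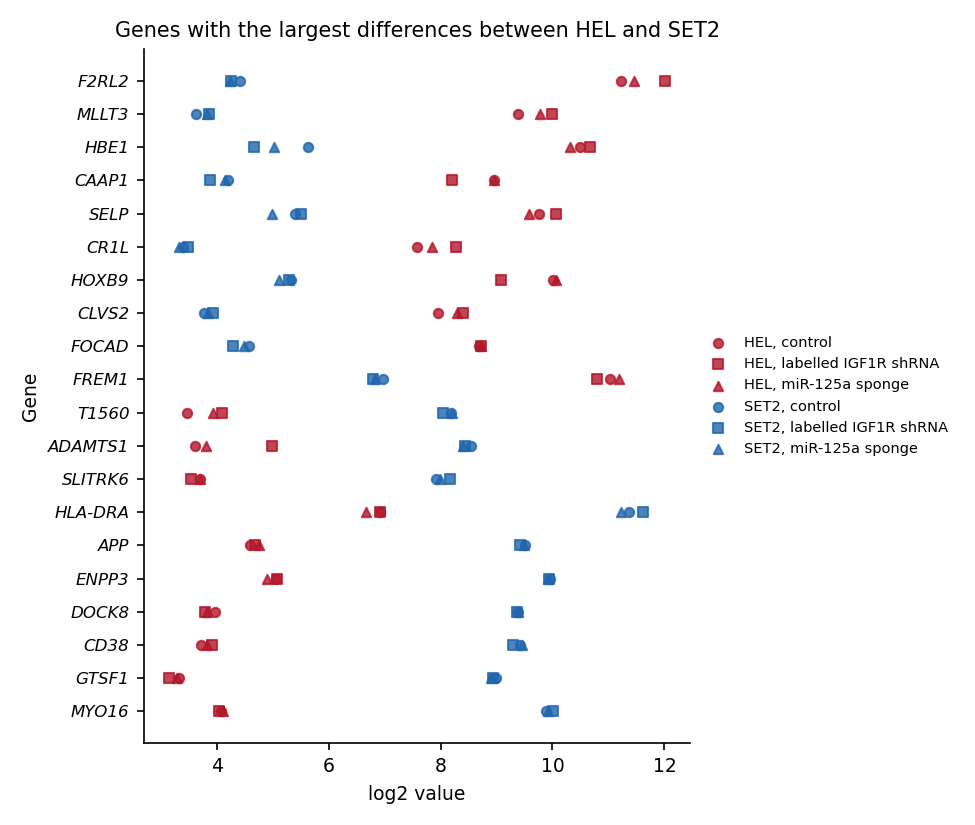
Log2 values on each of the 6 arrays for the 20 named genes that differ between HEL and SET2, with HEL in red, SET2 in blue and the treatment by symbol. For each gene the 3 HEL arrays and the 3 SET2 arrays form separate clusters, F2RL2 at 11.22 to 12.02 against 4.24 to 4.41.

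Of the 32 megakaryocyte and platelet genes, 18 were higher and 2 lower in HEL over all genes, and 21 passed adjusted over the list alone (adjusted p = 9.87e-07 by camera, adjusted p = 0.586 with an estimated correlation). SELP, PLEK (3.54), the collagen receptor gene ITGA2 (3.39) and GP9 (3.21) led. In the ATF4 list 12 genes were higher and 1 lower, and 16 passed adjusted over the list alone (adjusted p = 4.37e-05, adjusted p = 0.655 with an estimated correlation), among them CHAC1 (2.01), PSAT1 (1.90), SESN2 (1.65) and SLC7A5 (1.63). In the interferon list 2 were higher and 14 lower, and 20 passed adjusted over the list alone (adjusted p = 0.000132, adjusted p = 0.655 with an estimated correlation). IFI27 (-4.12), BST2 (-3.57) and IFI44L (-3.24) were lower in HEL, but MX2 was higher (2.87). In IGF-1 and insulin signalling 3 were higher and 11 lower, and 15 passed adjusted over the list alone (adjusted p = 0.00268, adjusted p = 0.655 with an estimated correlation). IGFBP7 (-2.46), the insulin receptor gene INSR (-2.24), IGFBP4 (-2.18) and SOS1 (-1.34) were lower in HEL. In cholesterol synthesis 5 genes were lower and 0 higher, and 7 passed adjusted over the list alone (adjusted p = 0.00339, adjusted p = 0.848 with an estimated correlation), with HMGCS1 at -2.07 and CYP51A1 at -1.69. Among proteasome subunits 1 was higher and 9 lower, and 12 passed adjusted over the list alone (adjusted p = 0.0163, adjusted p = 0.655 with an estimated correlation). Ribosome biogenesis was higher in HEL (0.25, adjusted p = 0.0294, adjusted p = 0.655 with an estimated correlation), with 7 genes higher and 1 lower and 9 adjusted over the list alone, NPM1 at 1.12.

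Cholesterol synthesis did not pass without control replicate 1 or 2 (-0.40, adjusted p = 0.0555), where glycolysis and hypoxia did (0.29, adjusted p = 0.0488). Proteasome subunits did not pass without sponge replicate 1 or 2 (-0.21, adjusted p = 0.0775) and ribosome biogenesis, at 0.25 with all arrays, did not without IGF1R shRNA replicate 1 or 2 (0.21, adjusted p = 0.0827). With dim genes left out neither passed (adjusted p = 0.0792 and 0.0681), while their means stayed at -0.25 and 0.25. The remaining 17 lists did not pass. Erythroid genes went both ways, with 8 higher and 10 lower in HEL over all genes and 19 passing adjusted over the list alone. HBE1 and RHD (2.18) were higher in HEL, and SLC4A1 (-2.82) and the fetal globin gene HBG1 (-2.25) were higher in SET2. Stem cell and progenitor genes were divided as well, 4 higher and 4 lower and 9 adjusted over the list alone, with MLLT3 against CD34 (-4.19) and ERG (-2.42). Among published miR-125 targets 6 were higher and 4 lower, and 10 passed adjusted over the list alone, with ETS1 at 3.12 and LIN28B at 2.97. In monocyte and granulocyte genes 5 were higher and 4 lower, and 11 passed adjusted over the list alone, with MS4A3 at 2.44 and ITGAM at -2.58. In FOXO targets 3 were higher and 9 lower, and 13 passed adjusted over the list alone, with FOXO1 at -2.15. Fry called 6 lists, of which megakaryocyte genes and IGF-1 and insulin signalling were also called by camera, and FOXO targets, JAK2-STAT5 targets, monocyte and granulocyte genes and miR-125 targets were not. Mean and median differed in sign for mitosis, heat shock, NF-kB, erythroid, lymphoid and stem cell genes, and camera ranked the ZFAND family upward at a mean of -0.10.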

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

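Of the tests in this part, those on saturation, on a trend with expression level and on other splits of the arrays were written down before their results were seen, and the other tests were chosen only after the result was seen.

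The lines stood on opposite sides, each with 1 array against 1, in 3 results of the targeted genes and, among the lists, in 2 whose medians also lay beyond the 2.5 and 97.5 percentiles of the random lists in opposite directions. The difference between the lines was not tested for any of these 5. Other lists with means of opposite sign did not reach those percentiles in both lines, such as ER stress and ERAD (0.25 in HEL and -0.17 in SET2) and heat shock (0.14 and -0.16) in the arrays labelled IGF1R shRNA. IGF1R in the arrays labelled IGF1R shRNA stood at -0.0745 in HEL and 0.011 in SET2, a difference of -0.0859. Both values were smaller in size than the SE of their average, 0.15, so their signs carry little weight. ZFAND2B in the same arrays stood at -0.346 and 0.12, a difference of -0.4705. ZFAND2B in the sponge arrays stood at -0.16 and 0.013, a difference of -0.17. Both values were smaller in size than the SE of their average, 0.17. The 4 brighter ZFAND2B probe sets had medians of -0.145 and -0.30 there, lower in both lines, so the opposite signs hold for the gene average only. The cholesterol synthesis list in the arrays labelled IGF1R shRNA stood at 0.63 and -0.43, a difference of 1.053. The interferon response list in the same arrays stood at 0.19 and -0.23, a difference of 0.42.

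The first pattern weighed is that IGF1R was not detectably lower in the arrays labelled IGF1R shRNA. If the shRNA lowers the transcript, an exchange of labels within a line would leave another array of that line with lower IGF1R. The largest median difference of the 15 bright IGF1R probe sets between a pair of arrays of one line was 0.10. This speaks only against an exchange that hides a fall of IGF1R. If the shRNA left the transcript unchanged, the test cannot decide whether labels were exchanged. A fall hidden by dim probe sets would show in the bright ones, and their median average change was 0.045. Saturation of bright probe sets stays open, because among the 56767 probe sets in the range of the bright IGF1R probe sets, 8.27 to 11.8, 58 were lower by at least 1 in both lines, which shows that falls are measurable there but lies between the bounds of 10 and 100 set beforehand. No biological explanation was tested.

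The second pattern is a run of zinc finger genes on chromosome 19, ZNF486 to ZNF257, with a median of 0.85 (SD 0.87, 15 genes, 7 of them at 1 or more) in the HEL array labelled IGF1R shRNA. The search for such runs was defined after an earlier look at all genes; ZNF429 stood at 2.44, ZNF257 at 2.30 and ZNF43 at 2.25, and the block was lower in HEL than in SET2, by a median of -2.61 with 13 of 15 genes called. Sequence shared by all zinc finger genes of the chromosome would lift the 210 others by a like amount, and their median was 0.22. For zinc finger genes of other chromosomes it was 0.026. Sequence shared mainly within this cluster was not tested and stays open. An effect of the shRNA in both lines would lift the block in SET2, where its median was -0.075. SET2 RNA mixed into the array would lift the 28 genes at least 4 lower in HEL, whose median was 0.017. A gain that reaches past the block cannot be told apart, because the 20 flanking genes had a median of 0.39 and mostly belong to the same cluster, while the 3 flanking genes without zinc finger symbols had -0.29. No biological explanation was tested.

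The third pattern is the lower ATF4 and amino acid response in the arrays labelled IGF1R shRNA. A control array that stands high would lower both treatments alike, but in HEL the list stood at -0.93 in the shRNA array and -0.074 in the sponge array, 0.86 apart (SD 0.99 over 21 genes, 17 of them lower in the shRNA array). In SET2 the values were -0.35 and -0.19, 0.15 apart (SD 0.29, 15 of 21 lower), which is between the bounds of 0.1 and 0.3, so a high control array stays open as a cause there. A trend of change with expression level within the array pairs would vanish on detrending, and the mean was then -0.60 (-0.93 in HEL and -0.27 in SET2). Whether the lower list comes from the shRNA, from the culture or from its medium was not tested. IGF1R itself was not detectably lower, and each line has 1 array.

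For the difference between HEL and SET2, 1 of the 10 splits of the 6 arrays into groups of 3, the real one, gave as many genes. The real split called 5475 and the highest of the others 0. With 10 splits a share under 0.05 cannot be reached. Of the 10, 4 splits part all the arrays of a treatment as the real one does. The 3 others of that kind place arrays of both lines in each group, and they called 0. The fits of the other splits had no cell line term, so the difference between the lines widened their spread. That alone brings their counts toward 0, so these counts do not bear on whether the real split arose by chance.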

How the results depend on the processing

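Every alternative in this part was planned except the test of each probe set by itself, which was chosen after the data had been seen. Of 1965 values recomputed, 1802 kept their direction and their side of the threshold, or stayed within the bound set for a count or a correlation. The main results were counts of genes and lists, correlations, IGF1R under IGF1R shRNA and ZFAND2B under the sponge. Of these 141 values, 107 were kept and 34 were not, against 1695 kept of the other 1824. A list that did not pass in either case counts as kept whatever its sign. No gene passed for either treatment under quantile normalisation, centring, the median or brightest probe set, without dim genes, with trend and robust variances, with the 4 arrays of a contrast or with each probe set tested by itself (0 of 259224 in limma for both, with 16215 and 10158 at unadjusted p under 0.05). Without the cell line block the counts were 0, 0 and 0 for shRNA, sponge and their difference. Arrays left out in turn gave 0 to 729 genes for IGF1R shRNA, 0 to 0 for the sponge, 0 to 670 for their difference and 2871 to 6330 for HEL against SET2; the highest treatment counts came without IGF1R shRNA replicate 2, when fewer arrays carry the spread, and their cause was not tested. The share of called genes higher in HEL stayed between 44.7% and 48.5%. A size of 2-fold with the same sign in both lines, without a test, gave 74, 13 and 65 genes. The brightest probe set gave 2613 for HEL against SET2. The IGF1R change under IGF1R shRNA reversed with the median of its probe sets (0.15), with each probe set on its own (median 0.0375) and in SET2 alone (0.011), and ran from -0.11 to 0.042 with arrays left out. The ZFAND2B change under the sponge reversed with the brightest probe set (0.025) and in SET2 alone (0.013), and ran from -0.23 to 0.088; under IGF1R shRNA it reversed in SET2 alone (0.12) and ran from -0.30 to 0.082. Under the sponge, the brightest probe set reversed IGF1R (-0.005), MRPS28 (-0.08), NEURL4 (0.19) and MT1F (0.28), and the median of the probe sets HSD17B7 (-0.03). Called lists numbered 2 to 8 for IGF1R shRNA, 1 to 2 for the sponge, 4 to 6 for their difference and 6 to 7 for HEL against SET2 with arrays left out. An estimated correlation called 0 for each of these; fry called 1 for IGF1R shRNA and 0 for the difference between treatments, which kept 2 without dim genes. Leaving out dim genes moved the correlation between lines to 0.028 (IGF1R shRNA) and 0.0707 (sponge) and that between treatments to 0.326, and Spearman's rho of the last was 0.377. The causes of these moves were not tested. Signal over background could not be judged, so values near the lower end of the scale are the least certain.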

Other observations

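The genes of this part were chosen after their values were seen. A stretch of chromosome 9 from NFIB to FOCAD differed between the lines as a block. Of its 21 protein-coding genes, 16 were higher and 2 lower in HEL, with a median log2 difference of 1.91 against 0.0076 for all genes. MLLT3 (5.94), FOCAD (4.26), FREM1 (4.13), NFIB (3.25), the chromatin-binding gene PSIP1 (2.64) and the ribosomal protein gene RPS6 (2.33) were higher in HEL. Elsewhere on the chromosome, CAAP1 was higher in HEL by 4.63, while DOCK8 (-5.52) and KANK1 (-2.25) were lower. JAK2, also on chromosome 9, did not pass the test (0.27, adjusted p = 0.144 by limma).

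Small nucleolar RNAs of imprinted clusters stood apart as well. The 18 SNORD116 genes had a median of -1.54 in the HEL array labelled IGF1R shRNA, where all 18 were lower, and of 0.63 in SET2, where 14 were higher; in the sponge arrays the medians were -0.255 and 0.115. The 31 SNORD114 genes were lower in HEL than in SET2 by a median of -3.10, and 29 of them were called. The difference in SNORD116 between the lines' responses was not tested.

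Probe sets outside the gene averages gave no calls either. Among the 80519 without a listed gene, limma called 0 for IGF1R shRNA and 0 for the sponge, with 4711 and 3342 at unadjusted p under 0.05. Among the 13116 with several symbols it called 0 and 0, with 783 and 503 at unadjusted p under 0.05.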
